A study of Mus musculus with 6 samples.

How the data were processed

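The series measured messenger RNA in fibro-adipogenic progenitors (FAPs), the mesenchymal progenitor cells of skeletal muscle that carry the surface receptor Pdgfra. Per the labels, the cells came from the plantaris muscle of C57BL/6 mice, 1000 sorted cells went into each tube, and libraries followed the published CEL-Seq2 type of protocol, in which transcripts are tagged near their 3' end before amplification. There were 3 libraries from sham muscle and 3 from overloaded muscle. How the load was applied and for how long is not given in the sources used here. The labels do not say whether the replicates came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

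The authors deposited 1 table of raw read counts per gene, whole numbers that had not been normalised, with 54100 Ensembl gene identifiers and a symbol for each. Per the submitters' processing notes, the tools were Trim Galore 0.6.6, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.28.1, with the GRCm38 mouse genome build. The annotation release, the strand setting, the treatment of reads that map to several places and any use of molecular identifiers are not given in the sources used here. Without a stated strand setting, reads of a gene and of a gene on the opposite strand cannot be told apart where their exons overlap. Of the 114 genes chosen for description, 39 had exons that overlap those of another gene on either strand. Overlaps on the same and on the opposite strand were not counted apart. Ribosomal protein genes share sequence with many pseudogenes and their counts are uncertain. If molecular identifiers were not collapsed, reads are not independent molecules, so the intervals and floors given with the values cover counting error only. Gene positions were taken from GENCODE M21, the mouse annotation on GRCm38, which held all 54100 identifiers. Genes were handled by identifier, because some symbols occur more than once.

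Total counts were 720326, 500402 and 754456 in sham libraries 1 to 3 and 1124210, 850857 and 893025 in overloaded libraries 1 to 3. At least 1 count was present for 28251 genes. The filterByExpr function of edgeR, with a minimum count of 10 and a minimum total of 15, kept 7207 genes for testing. CPM (counts scaled to a total of 1e6) were computed here from the deposited counts, relative to the counts in the tested genes after scaling by the trimmed mean of M-values (TMM). A floor of 3 counts over a whole group corresponded to 1.56 CPM in sham and 1.11 CPM in overloaded libraries. For a gene with 0 counts in a group, a fold change is given as a lower bound against that floor. For a gene with 1 to 3 counts in a group, the ratio is given with an exact 95% interval for the counts. The biological coefficient of variation was 21.2% and the median standard error of a log2 fold change was 0.33.

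Overloaded and sham libraries were compared with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with robust dispersions and Benjamini-Hochberg adjustment over the 7207 genes. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was obtained as its size divided by the square root of the F statistic. The comparison, its tests, 25 gene lists, 8 lists of markers of other cell types, the rule for the genes named and the alternative settings were chosen before the data were examined. Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, again with the correlation estimated from each list, and with fry, which asks whether the genes of a list move on balance in 1 direction. Marker lists were summed as CPM per library and compared by an exact two-sided permutation test on log2(sum + 1). With 3 libraries against 3 this test cannot give a p under 0.1.

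The genes named were the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 10 CPM and no overlap between the groups, passing over predicted gene models. Pdgfra, Yap1, Wwtr1, Thbs1, Ccn1, Ccn2 and Ankrd1 were named whatever their values, as were up to 4 called members of each gene list in order of adjusted p. Any other gene is said to have been picked after its values were seen.

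The test was checked on simulated counts for 7207 genes with the means and library sizes of this comparison, with 200 genes changed. In the data a larger share was called, 29.3% of the genes tested, so the recovery shares of the simulation need not hold there. At a simulated fold of 4, 187 of the 200 genes (93.5%) were recovered and 4.59% of the calls were false. At a fold of 2, 70 genes (35%) were recovered and 13.6% of the calls were false, and at a fold of 1.5, 2 genes (1%) were recovered. Among 20 simulated random lists camera called 1 at the preset correlation and 0 with the estimated correlation. A simulated list that had been shifted was called at the preset correlation and was missed with the estimated one.

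Alternatives were DESeq2 size factors, library size only and upper quartile factors for scaling, no filter or a minimum count of 30, the Wald test of DESeq2 1.42.0, limma-voom, dispersions without the robust option, the replicate number as a block, libraries thinned to the smallest total, an adjusted p of 0.01, a test against a fold of 1.5, mitochondrial and ribosomal protein genes left out, and each library left out in turn. A covariate for the share of background reads was added after the data had been seen. Single named genes were run under 11 of these settings as planned, and under the other 10 as a step added after the data had been seen.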

Results

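RNA was sequenced from FAPs of sham and of overloaded plantaris, a calf muscle that extends the ankle, with 3 libraries in each group. Total counts per library ranged from 500402 to 754456 in sham and from 850857 to 1124210 in overloaded muscle, a difference in depth at the smallest p that an exact permutation test of 3 against 3 can give (p = 0.1). Libraries of one group differed from each other by more than sampling noise, with a chi-square per degree of freedom of 4.30 to 7.77, so none was a copy of another. Across genes, the correlation of log2 CPM was 0.913 to 0.938 within groups and 0.759 to 0.833 between them. The leading principal component held 61.6% of the variance and placed sham libraries between -39.7 and -32.8 and overloaded libraries between 31.8 and 46.4. The single comparison asks how transcript levels in FAPs differ when the muscle bears more load.

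Among genes with enough counts to test in FAPs of overloaded and sham muscle, 10 of 17 matricellular genes, 15 of 26 chemokine and cytokine genes and 21 of 31 actin and myofibroblast genes rose with overload. So did 10 of the 11 mitosis genes tested, of 34 on the list, and 15 of 21 markers used to recognise FAPs fell. Each of these lists was called by camera at the preset correlation and none with an estimated correlation (lowest adjusted p = 0.0518 with an estimated correlation). Tnc, which encodes the matrix glycoprotein tenascin-C, rose from 7.42 ± 1.77 to 1566 ± 274 CPM (SD, n = 3 in each group), a log2 fold change of 7.71 with a standard error (SE) of 0.31 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.62e-18). Ccl2, a chemokine that attracts monocytes, rose from 2046 ± 314 to 24479 ± 2185 CPM, and Acta2, the smooth muscle actin of myofibroblasts, from 15.1 ± 6.83 to 321 ± 101 CPM. Inmt, which encodes indolethylamine N-methyltransferase, fell from 2047 ± 18.4 to 112 ± 59.0 CPM, and Dcn, which encodes the collagen-binding proteoglycan decorin, from 20310 ± 1611 to 8208 ± 476 CPM.

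Of 7207 genes tested, 1084 were higher and 1027 lower in overloaded FAPs by edgeR's quasi-likelihood test at an adjusted p under 0.05, or 29.3% of those tested. The log2 fold change was above 1 for 700 of the higher genes and below -1 for 723 of the lower ones. The groups did not overlap for 2992 of the tested genes (41.5%, where chance gives 10%), and these included 2013 of the 2111 called genes. Protein-coding genes made up 1076 of the higher and 982 of the lower genes, and predicted gene models 12 and 35. Adding the share of background reads in each library as a covariate, a step chosen after the data were seen, left 488 higher and 381 lower genes.

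**Figure D1:**
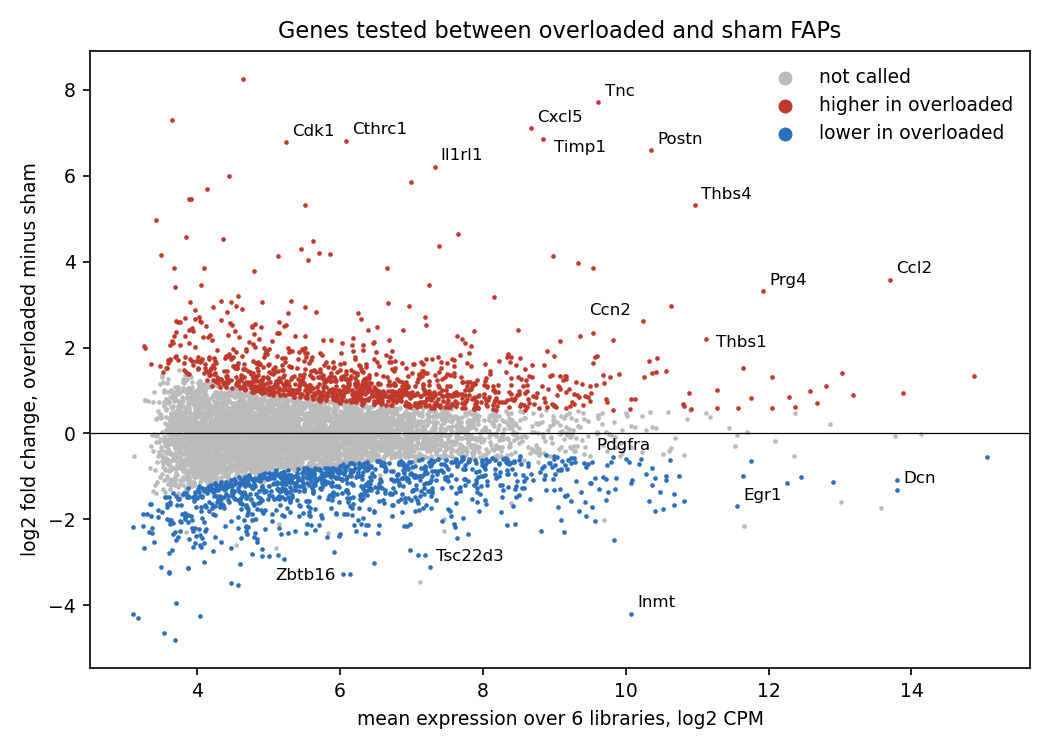
Log2 fold change, overloaded minus sham, against mean log2 CPM over the 6 libraries for the 7207 genes tested, each point 1 gene, with 1084 higher genes in red, 1027 lower genes in blue and the others in grey. Tnc lies at 7.71 and Inmt at -4.19, and the fitted fold changes of genes with 3 or fewer counts in a group depend on the prior count and are no measure of size.

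Besides Tnc (chromosome 4, 63959785 to 64047015), the genes with the largest rise included Postn, which encodes the matrix protein periostin (chromosome 3, 54361109 to 54391037), at 27.5 ± 11.9 CPM in sham and 2592 ± 413 CPM in overloaded FAPs, a log2 fold change of 6.58 (SE 0.29). Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874735), rose from 7.79 ± 3.26 to 916 ± 116 CPM, a log2 fold change of 6.85 (SE 0.31). Cxcl5, a chemokine for neutrophils (chromosome 5, 90759360 to 90761624), rose from 6.02 ± 2.14 to 816 ± 381 CPM, a log2 fold change of 7.11 (SE 0.40). Il1rl1, the receptor for interleukin 33 (chromosome 1, 40429570 to 40465415), reached 318 ± 51.0 CPM from 3.82 ± 6.61 CPM, with all 8 of its sham counts in sham library 1, so that the size of its fold change rests on that library. For 5 genes the sham libraries together held 2 counts or fewer. Npy, the neuropeptide Y gene (chromosome 6, 49822710 to 49829507), had 0 counts in sham and 127 in overloaded libraries and was at least 30.1-fold higher. Its overloaded libraries stood at 19.2, 92.8 and 38.2 CPM. Ltbp2, a latent TGF-beta binding protein (chromosome 12, 84783212 to 84876532), had 0 and 69 counts and was at least 16.4-fold higher. Cthrc1, a secreted protein of activated fibroblasts (chromosome 15, 39076932 to 39087121), had 2 and 364 counts, a ratio of 130 with a 95% counting interval of 35.6 to 1074. The mitotic kinase gene Cdk1 (chromosome 10, 69335146 to 69352938) had 1 and 200 counts, a ratio of 142 with an interval of 25.3 to 5653. Cxcl3, another neutrophil chemokine (chromosome 5, 90786103 to 90789600), had 1 and 117 counts, a ratio of 83.3 with an interval of 14.7 to 3319.

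Among the genes with the largest fall, Inmt (chromosome 6, 55170626 to 55175043) fell by 4.19 on the log2 scale (SE 0.35). Cyp27a1, a sterol 27-hydroxylase (chromosome 1, 74713574 to 74737892), fell by 4.25 (SE 0.64) from 31.5 ± 15.2 to 1.51 ± 0.711 CPM. Zbtb16, a zinc finger transcription factor (chromosome 9, 48654297 to 48836222), fell by 3.27 (SE 0.34) from 128 ± 40.1 to 13.1 ± 6.38 CPM. Cbfa2t3, a transcriptional corepressor (chromosome 8, 122625141 to 122699109), fell by 3.52 (SE 0.52). Nmb, which encodes the peptide neuromedin B (chromosome 7, 80902227 to 80905076), fell by 3.27 (SE 0.33) from 120 ± 27.6 to 12.5 ± 4.37 CPM. Shisa3 (chromosome 5, 67607882 to 67623552) fell by 3.23 (SE 0.60). Galnt15, a glycosyltransferase (chromosome 14, 32028989 to 32062197), fell by 3.14 (SE 0.58), and its log2 fold change was -3.75 without overloaded replicate 1. Irgm2, an interferon-inducible GTPase (chromosome 11, 58199618 to 58222782), fell by 3.25 (SE 0.63), and its log2 fold change was -4.0 without overloaded replicate 1. Lvrn, an aminopeptidase (chromosome 18, 46850038 to 46907242), had 47 counts in sham and 2 in overloaded libraries, a ratio of 33.0 with a 95% counting interval of 8.64 to 280. Dnah3, a dynein heavy chain (chromosome 7, 119922671 to 120095280), had 42 and 2 counts, a ratio of 29.5 with an interval of 7.67 to 251. Exons of Tnc, Ltbp2, Dnah3, Cbfa2t3, Nmb, Irgm2 and Shisa3, and of Thbs1, Ccn2, Pdgfra and Yap1 described next, overlap exons of another annotated gene, and their counts are uncertain to that extent.

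Among the genes fixed in advance, Thbs1, which encodes the matricellular protein thrombospondin-1 (chromosome 2, 118111876 to 118127133), rose from 797 ± 128 to 3654 ± 357 CPM, a log2 fold change of 2.2 (SE 0.20, edgeR adjusted p = 1.09e-09). Ccn2, a matricellular protein and a target of the transcriptional coactivators YAP and TAZ (chromosome 10, 24595442 to 24598683), rose from 341 ± 61.4 to 2095 ± 324 CPM, a log2 fold change of 2.62 (SE 0.21, edgeR adjusted p = 6.79e-11). Ccn1, another target of the same coactivators (chromosome 3, 145646976 to 145649981), was at 232 ± 78.9 and 288 ± 104 CPM and did not pass the test (edgeR adjusted p = 0.423). Ankrd1, a further target (chromosome 19, 36111961 to 36120099), had 2 counts in sham and 4 in overloaded libraries, too few to test. The gene for YAP itself, Yap1 (chromosome 9, 7931999 to 8004596), was at 103 ± 13.0 and 68.5 ± 9.61 CPM (log2 fold change -0.60, SE 0.25, edgeR adjusted p = 0.0643). Wwtr1, the gene for TAZ (chromosome 3, 57455649 to 57575910), was at 169 ± 32.1 and 216 ± 23.3 CPM (log2 fold change 0.35, SE 0.22, edgeR adjusted p = 0.244). Pdgfra, the receptor by which the cells were defined (chromosome 5, 75152292 to 75198215), was at 857 ± 143 and 594 ± 172 CPM (log2 fold change -0.53, SE 0.21, edgeR adjusted p = 0.0624). Yap1 passed the threshold with scaling by library size only (edgeR adjusted p = 0.0393) and with a minimum count of 30 (0.0468), with a range over 21 alternatives from 0.0393 to 0.547. Pdgfra passed it in 8 of the 21, among them the replicate number as a block (edgeR adjusted p = 0.0450), the block with thinning (0.0335), library size only (0.0386), without overloaded replicate 3 (0.0198) and with the background covariate (log2 fold change -1.12, 0.00902). Over the 21 alternatives its adjusted p by edgeR, DESeq2 or limma-voom ranged from 0.00902 to 0.671.

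**Figure D2:**
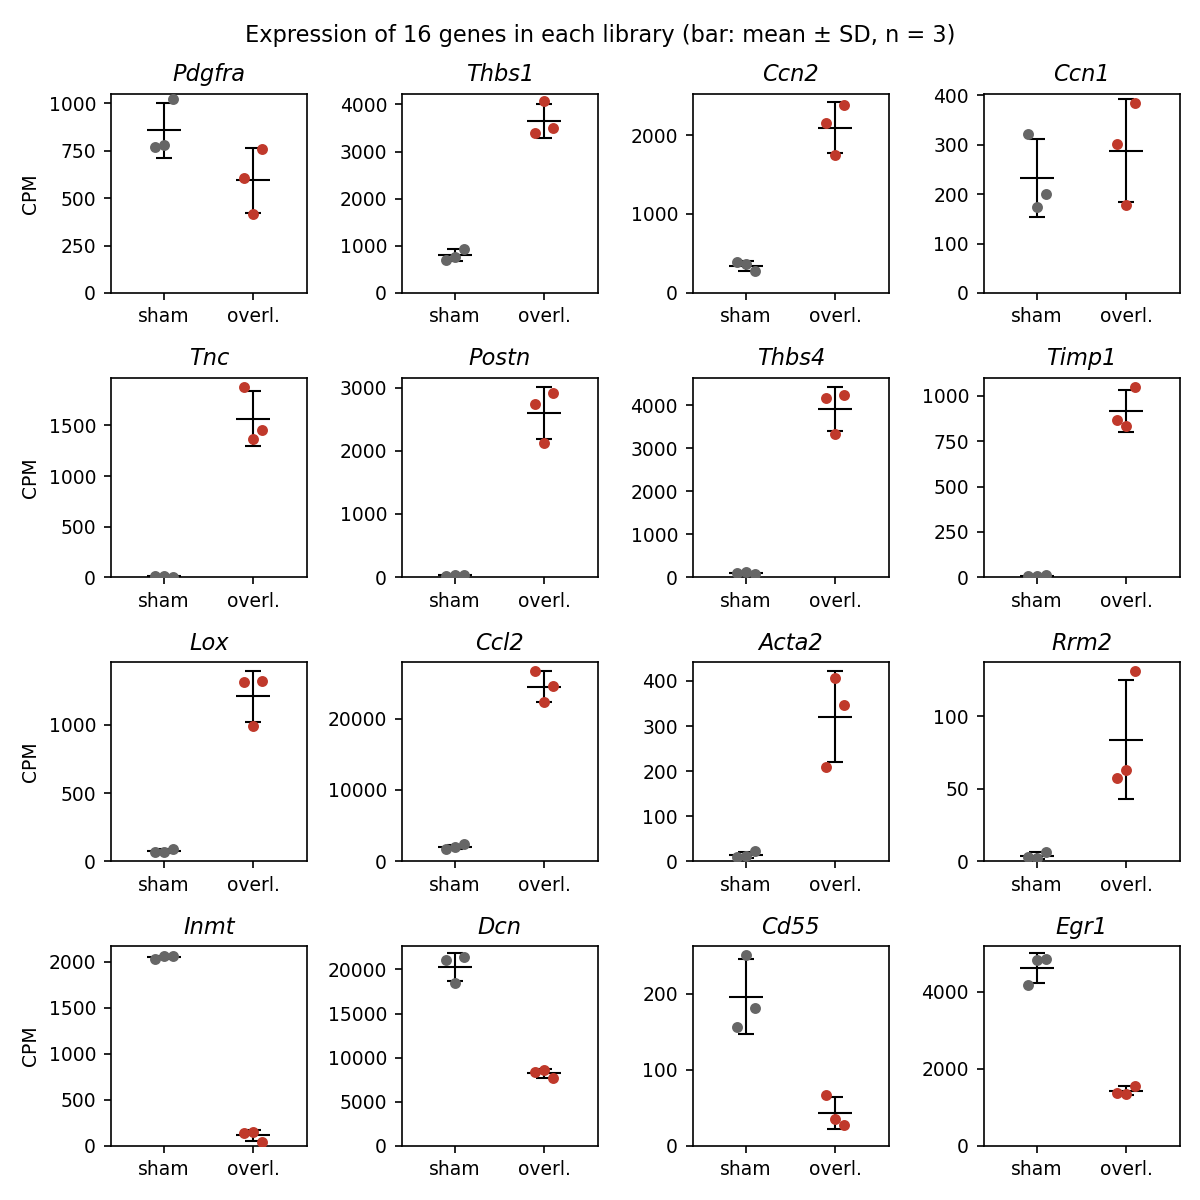
CPM of 16 genes in each library, with grey points for the 3 sham and red points for the 3 overloaded libraries and a bar for the mean ± SD on linear axes that start at 0. Thbs1 rose from a mean of 797 to 3654 CPM and Ccn2 from 341 to 2095 CPM, while the groups for Ccn1, with means of 232 and 288 CPM, overlap.

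Of the 25 gene lists, camera at the preset correlation called 12 higher and 6 lower in overloaded FAPs. With a correlation estimated from each list it called 0, the lowest adjusted p being 0.0518, although 11 lists had an unadjusted p under 0.05. Fry called 22 lists, but unlike camera it does not set a list against the other genes. With 29.3% of the genes tested called, a list can pass fry without changing more than the rest. With the background covariate the counts of most lists fell, for example from 10 to 5 higher for DNA replication, from 10 to 4 lower for interferon-stimulated genes and from 27 to 10 higher for ribosomal proteins. With a minimum count of 30, where fewer of these genes are tested, DNA replication and mitosis each had 2 higher genes. These lists hold 36 and 34 genes, most of them with too few counts to test, and without the count filter 14 and 16 were higher, while after thinning mitosis had 6. The filter keeps a gene with enough counts in only the overloaded libraries, such as Cdk1 with 1 count in sham and 200 in overloaded. The share of tested members that rose is thus partly set by the filter.

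Matrix genes moved in both directions, and the classes were not tested against each other. Of 17 matricellular genes tested, 10 rose, 4 fell and 3 were not called, and the count adjusted over the list alone was 10 and 4 (camera adjusted p = 0.00125, adjusted p = 0.0919 with an estimated correlation). Thbs4, encoding thrombospondin-4, rose from 99.2 ± 14.7 to 3915 ± 513 CPM, and Ccn4 by a log2 fold change of 3.85 (SE 0.31). The 4 that fell, picked after their values were seen, were Ccn3 (log2 fold change -2.70), Tnxb (-1.34), Smoc2 (-1.04) and Fbln5 (-1.0). Of 35 genes for fibrillar collagens and their processing, 21 rose, 0 fell and 14 were not called, with 22 higher when adjusted over the list alone (camera adjusted p = 2.58e-07, adjusted p = 0.0919 with an estimated correlation). Lox, an enzyme that crosslinks collagen, rose from 77.1 ± 14.0 to 1208 ± 185 CPM, and Col8a1 from 97.9 ± 24.3 to 1403 ± 124 CPM. Col12a1 rose by a log2 fold change of 2.17 (SE 0.28) and the collagen lysyl hydroxylase Plod2 by 1.77 (SE 0.21). Of 16 basement membrane genes, 9 fell, 0 rose and 7 were not called, with the same 9 when adjusted over the list alone (camera adjusted p = 0.00188, adjusted p = 0.334 with an estimated correlation). Nid1, which encodes the linker protein nidogen-1, fell from 2051 ± 396 to 800 ± 235 CPM, and the laminin gene Lama2 from 329 ± 54.4 to 143 ± 65.1 CPM (log2 fold change -1.19, and -1.10 and not called with the background covariate). Without sham replicate 3 the list had 4 lower genes, and without overloaded replicate 3 it had 5. Markers of endothelial cells, another source of basement membrane, summed to 196 ± 94.4 CPM in sham and 88.5 ± 50.7 CPM in overloaded libraries. Tek held the most counts of that list in every library, 89, 51 and 93 in sham and 33, 19 and 22 in overloaded. Pecam1 had 7, 4 and 2 counts in sham and 5, 4 and 1 in overloaded libraries. Tek made up most of the counts in sham libraries 2 and 3 and in overloaded library 3. In sham library 1 and overloaded libraries 1 and 2 the other markers together held more, with Flt1 at 38, 20 and 18 counts. With few counts for most markers, the sum does not tell whether endothelial cells became fewer. Of 21 matrix proteases and inhibitors, 6 rose, 7 fell and 8 were not called, or 7 and 8 when adjusted over the list alone. Camera did not call the list (adjusted p = 0.556). Besides Timp1, which rose as given earlier, the protease gene Htra3 fell by 1.80 on the log2 scale (SE 0.21).

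The markers by which FAPs are recognised fell in most cases. Of 21 tested, 15 fell, 2 rose and 4 were not called, or 17 and 3 when adjusted over the list alone (camera adjusted p = 4.64e-05, adjusted p = 0.212 with an estimated correlation). Clec3b fell by 2.34 on the log2 scale (SE 0.26), Cd55, a complement-regulating surface protein, by 2.15 (SE 0.29), Pi16 by 1.67 (SE 0.24) and Dcn by 1.31 (SE 0.19). The 2 that rose, picked after their values were seen, were Mfap5 (log2 fold change 1.32) and Cxcl14 (0.59). Reads of olfactory and vomeronasal receptor genes, which FAPs are not known to express, were more frequent in sham libraries, at 1420, 1785 and 778 CPM of the library total against 306, 1080 and 230 CPM in overloaded libraries, or 1328 ± 510 and 539 ± 471 CPM (exact permutation p = 0.2, where the smallest possible is 0.1).

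Of 31 genes of the actin cytoskeleton and of myofibroblasts, 21 rose, 0 fell and 10 were not called, with 22 higher when adjusted over the list alone (camera adjusted p = 1.17e-09, adjusted p = 0.0518 with an estimated correlation). Acta2 rose by a log2 fold change of 4.36 (SE 0.32) and Actn1, encoding the crosslinker alpha-actinin-1, by 3.46 (SE 0.29). Markers of pericytes and smooth muscle, a list that also holds Acta2, summed to 225 ± 38.2 CPM in sham and 499 ± 106 CPM in overloaded libraries, and without Acta2 to 210 ± 41.0 and 178 ± 38.9 CPM. Of 16 DNA replication genes, 10 rose, 0 fell and 6 were not called, with the same 10 when adjusted over the list alone (camera adjusted p = 3.71e-06, adjusted p = 0.0518 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 3.89 ± 2.49 to 83.7 ± 40.8 CPM, a log2 fold change of 4.29 that became 4.97 without sham replicate 3. E2f1, a transcription factor for S-phase genes, rose by 3.07 (SE 0.57), and the helicase gene Mcm2 went from 1 to 81 counts, a ratio of 57.7 with a 95% counting interval of 10.1 to 2306. Of 11 mitosis genes, 10 rose, 0 fell and 1, Cenpf, was not called, again with 10 when adjusted over the list alone (camera adjusted p = 1.06e-07, adjusted p = 0.106 with an estimated correlation). The centromere histone gene Cenpa went from 3 to 105 counts, a ratio of 24.9 with an interval of 8.30 to 123, and Anln, encoding the cytokinesis protein anillin, from 2 to 57 counts, a ratio of 20.3 with an interval of 5.37 to 172.

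Signalling genes split. Of 26 genes for chemokines, cytokines and their receptors, 15 rose, 3 fell and 8 were not called, or 16 and 3 when adjusted over the list alone (camera adjusted p = 0.000373, adjusted p = 0.106 with an estimated correlation). Ccl2 rose by a log2 fold change of 3.58 (SE 0.21) and Lif, a cytokine of the interleukin 6 family, by 4.64 (SE 0.36). The 3 that fell, picked after their values were seen, were Ccl11, Ptges and Cxcl10. Markers of leukocytes, which make many of these factors, summed to 30 ± 6.66 CPM in sham and 12.4 ± 6.03 CPM in overloaded libraries. Of 9 complement genes, 6 fell, 0 rose and 3 were not called, with 7 lower when adjusted over the list alone (camera adjusted p = 0.000523, adjusted p = 0.170 with an estimated correlation), among them C3, from 391 ± 31.0 to 190 ± 38.6 CPM, and C1s1, from 489 ± 63.4 to 226 ± 50.7 CPM. Of 20 interferon-stimulated genes, 10 fell, 0 rose and 10 were not called, with the same 10 when adjusted over the list alone (camera adjusted p = 0.00146, adjusted p = 0.0919 with an estimated correlation). The transcription factor Irf1 fell from 499 ± 53.9 to 203 ± 20.9 CPM and B2m, the light chain of class I histocompatibility molecules, from 1255 ± 243 to 609 ± 111 CPM (log2 fold change -1.04, and -0.67 and not called with the background covariate). Without overloaded replicate 1 the list had 8 lower genes and 1 higher. Of 32 immediate early and dissociation response genes, 18 fell, 6 rose and 8 were not called, or 19 and 6 when adjusted over the list alone (camera adjusted p = 0.00103, adjusted p = 0.101 with an estimated correlation). Egr1 fell from 4617 ± 382 to 1425 ± 117 CPM and Fosb from 1103 ± 59.8 to 290 ± 42.2 CPM, while Ier3 rose from 635 ± 44.2 to 2150 ± 308 CPM.

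Of 16 Wnt signalling genes, 8 fell, 1 rose and 7 were not called, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.00274, adjusted p = 0.0919 with an estimated correlation). The transcription factor gene Tcf7l2 fell from 327 ± 35.9 to 156 ± 37.1 CPM (log2 fold change -1.08, and -0.77 and not called with the background covariate). The ligand gene Wnt5a fell from 62.8 ± 8.28 to 26.6 ± 10.5 CPM (log2 fold change -1.23, which did not pass the stricter test against a fold of 1.5). The one that rose, picked after its values were seen, was the receptor gene Fzd1 (log2 fold change 1.16). Without sham replicate 3 the list had 5 lower genes and 0 higher. Of 29 TGF-beta and BMP signalling genes, 8 rose, 10 fell and 11 were not called, with the same counts when adjusted over the list alone. Camera did not call the list (adjusted p = 0.983). Inhba, which encodes the subunit of activin A, rose from 54.3 ± 11.4 to 956 ± 184 CPM, and Ltbp4 fell from 837 ± 190 to 307 ± 81.3 CPM. Of 23 secreted growth factor genes, 9 rose, 3 fell and 11 were not called, or 10 and 3 when adjusted over the list alone. Camera did not call the list (adjusted p = 0.165). Angptl4 rose by a log2 fold change of 4.21 (SE 0.44) and Csf1, a growth factor for macrophages, by 1.24 (SE 0.23, and 0.77 and not called with the background covariate), while Igfbp5, an insulin-like growth factor binding protein, fell by 1.29 (SE 0.20). Of 16 YAP and TAZ target genes, 3 rose, 4 fell and 9 were not called, or 3 and 5 when adjusted over the list alone. Camera did not call the list (adjusted p = 0.583). With Ccn2, those that rose were Ccdc80 (log2 fold change 0.93) and, picked after its values were seen, Tgfb2 (0.60), and those that fell were Asap1 (-1.15), F3 (-1.08) and, picked in the same way, Lats2 (-0.84) and Crim1 (-1.05). Ccdc80 and F3 did not pass the stricter test against a fold of 1.5, and F3 was at -1.11 and not called with the background covariate. Without the count filter 3 of the list rose and 2 fell, and without sham replicate 2 or sham replicate 3 there were 2 and 2.

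Of 34 genes for protein folding in the endoplasmic reticulum, 23 rose, 0 fell and 11 were not called, with 24 higher when adjusted over the list alone (camera adjusted p = 1.95e-08, adjusted p = 0.0518 with an estimated correlation). Pdia6, a disulfide isomerase, rose from 814 ± 97.8 to 2230 ± 413 CPM and the translocon subunit gene Sec61b from 19.4 ± 3.21 to 89.8 ± 15.5 CPM. Of 29 genes for ribosome biogenesis and the nucleolus, 18 rose, 1 fell and 10 were not called, or 18 and 2 when adjusted over the list alone (camera adjusted p = 5.33e-06, adjusted p = 0.0919 with an estimated correlation). Npm1, encoding nucleophosmin, rose from 310 ± 35.4 to 776 ± 178 CPM, and the gene that fell, picked after its values were seen, was Nop58 (log2 fold change -0.68). Of 76 cytosolic ribosomal protein genes, whose counts are uncertain for the reason given with the processing, 27 rose, 0 fell and 49 were not called, with 29 higher when adjusted over the list alone (camera adjusted p = 4.89e-05, adjusted p = 0.361 with an estimated correlation). Rps2 rose by a log2 fold change of 1.58 (SE 0.24) and Rpl5 by 1.31 (SE 0.21). Without sham replicate 3 the list had 16 higher and 2 lower genes.

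Of 18 glycolysis and hypoxia genes, 10 rose, 1 fell and 7 were not called, with the same counts when adjusted over the list alone (camera adjusted p = 0.00167, adjusted p = 0.170 with an estimated correlation). Ldha, which encodes a subunit of lactate dehydrogenase, rose from 71.6 ± 15.1 to 242 ± 58.5 CPM and Hif1a, a subunit of the hypoxia-inducible transcription factor, from 90.5 ± 20.2 to 296 ± 94.4 CPM, while Adm, picked after its values were seen, fell by 1.19 on the log2 scale. Of 14 cholesterol biosynthesis genes, 8 rose, 0 fell and 6 were not called, with the same 8 when adjusted over the list alone (camera adjusted p = 0.000762, adjusted p = 0.239 with an estimated correlation). Hmgcs1, a synthase early in the pathway, rose from 100 ± 21.2 to 262 ± 49.7 CPM and Msmo1, a sterol oxidase late in it, from 70.6 ± 28.5 to 188 ± 27.0 CPM. Of 43 oxidative phosphorylation subunit genes, 12 rose, 0 fell and 31 were not called, with the same 12 when adjusted over the list alone (camera adjusted p = 4.89e-05, adjusted p = 0.212 with an estimated correlation). Atp5g3 rose by a log2 fold change of 1.36 (SE 0.21) and Atp5a1 by 1.20 (SE 0.21), both subunits of ATP synthase. Without sham replicate 3 the list had 7 higher genes. Of 11 transcripts of the mitochondrial genome, 3 rose, 0 fell and 8 were not called, with 4 higher when adjusted over the list alone, and camera did not call the list (adjusted p = 0.106). These were mt-Nd6 (log2 fold change 1.1, SE 0.20), mt-Nd1 (0.98, SE 0.20) and mt-Atp6 (0.74, SE 0.24, edgeR adjusted p = 0.0204). Without sham replicate 3 the edgeR adjusted p of mt-Atp6 was 0.0920 and without overloaded replicate 3 it was 0.176. Over the alternatives in which mt-Atp6 was tested, its adjusted p by edgeR, DESeq2 or limma-voom ranged from 0.00731 to 0.479. Mitochondrial transcripts were not tested in the setting that left them out. The stricter test against a fold of 1.5 was not passed by mt-Nd1 (edgeR adjusted p = 0.0524) or by mt-Atp6 (0.343). Exons of mt-Nd6, mt-Nd1 and mt-Atp6 each overlap those of another mitochondrial gene, for mt-Nd6 on the opposite strand, and their counts are uncertain to that extent. Without 1 library the list had from 2 higher genes and 1 lower (without sham replicate 3) to 5 and 0 (without overloaded replicate 2). Of 15 genes for adipogenesis and lipid storage, 5 rose, 5 fell and 5 were not called, with the same counts when adjusted over the list alone, and camera did not call the list (adjusted p = 0.981). Lpl, encoding lipoprotein lipase, fell by 1.46 on the log2 scale (SE 0.21) and the lipocalin gene Apod by 1.55 (SE 0.25). Without sham replicate 2 the list had 2 higher and 5 lower genes, and without sham replicate 1 it had 5 and 3.

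**Figure D3:**
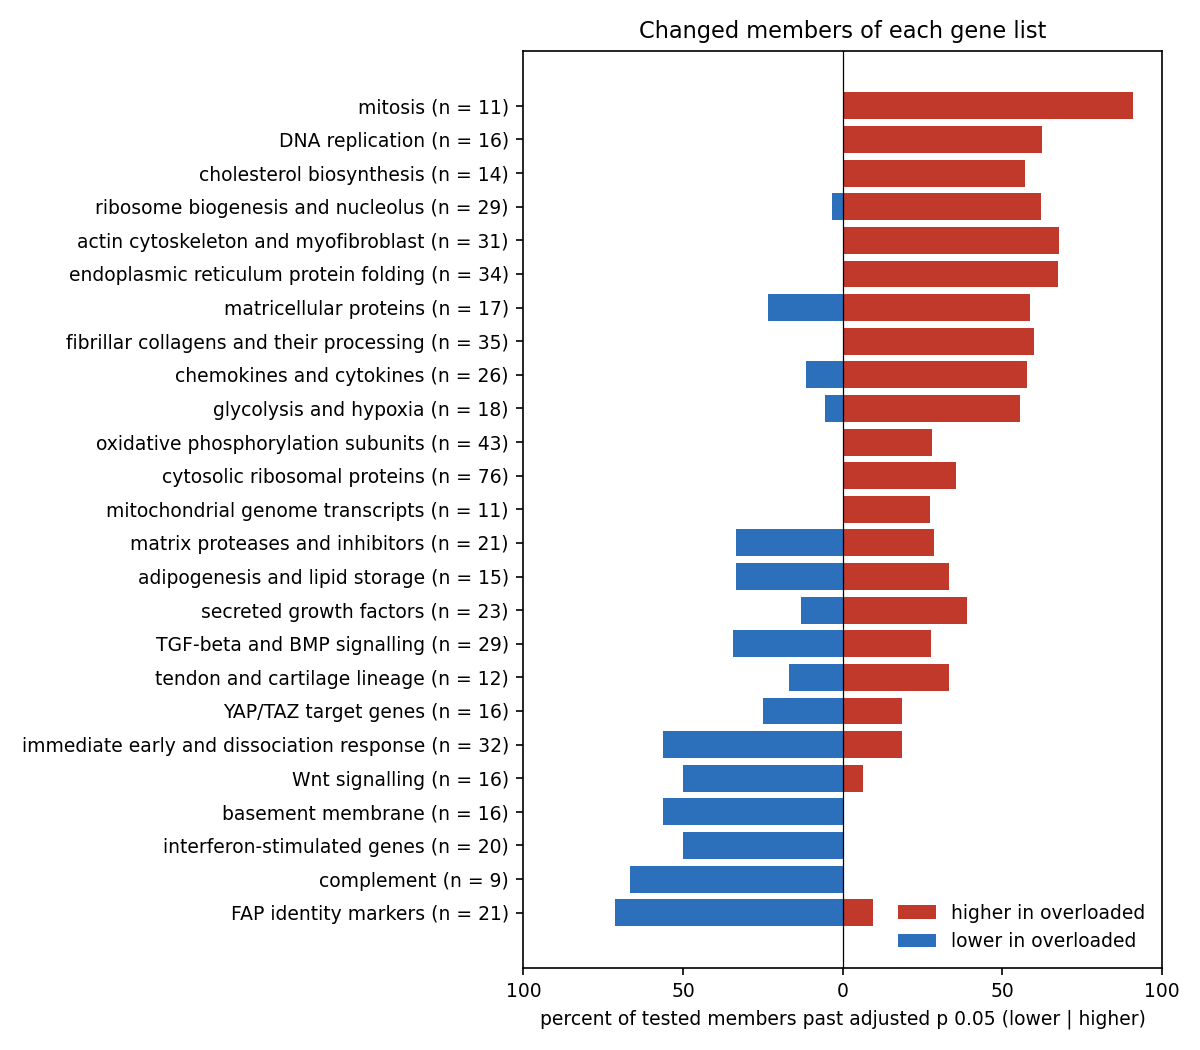
Percent of the tested members of each of the 25 gene lists that were called higher (red, to the right) or lower (blue, to the left) in overloaded FAPs, with the number tested beside each name and lists ordered by median log2 fold change. The mitosis list, with 10 of the 11 tested of its 34 members higher, lies at the top and the FAP markers, with 15 of 21 lower, at the bottom.

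Of 12 tendon and cartilage genes, 4 rose, 2 fell and 6 were not called, or 4 and 3 when adjusted over the list alone, and camera did not call the list (adjusted p = 0.274). The median log2 fold change was -0.12 and the mean 0.76. Besides Thbs4, Prg4, which encodes the joint lubricant lubricin, rose from 710 ± 108 to 7089 ± 1781 CPM and Cilp from 364 ± 65.4 to 2822 ± 150 CPM, and Runx2, picked after its values were seen, had a log2 fold change of 1.88. Egr1 and, picked in the same way, Angptl7 (log2 fold change -1.61) fell. The tenocyte markers, 10 genes of which 6 passed the count filter in FAPs, summed to 710 ± 79.5 CPM in sham and 6904 ± 687 CPM in overloaded libraries (exact permutation p = 0.1, adjusted p = 0.133 over 8 lists). Without Thbs4 and Cilp, the remaining 8 markers summed to 247 ± 16 and 167 ± 80.5 CPM, a fall that rests largely on Angptl7.

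Markers of other cells that the sort could have let through were also summed. Those of muscle fibres came to 69.3 ± 22.6 CPM in sham and 33.6 ± 2.25 CPM in overloaded libraries, and those of Schwann and perineurial cells, of which 2 of 12 passed the count filter, to 744 ± 155 and 482 ± 84.0 CPM. For these lists and those of endothelial cells, leukocytes and pericytes, the exact permutation p was 0.1, the smallest possible, and the adjusted p 0.133. Satellite cell markers summed to 662 ± 160 and 706 ± 273 CPM (exact permutation p = 0.9), and without Sdc4, a syndecan, to 168.5 ± 23.2 and 71.6 ± 29.6 CPM. Red blood cell markers summed to 65.4 ± 64.5 and 12.2 ± 13.5 CPM (exact permutation p = 0.5).

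**Figure D4:**
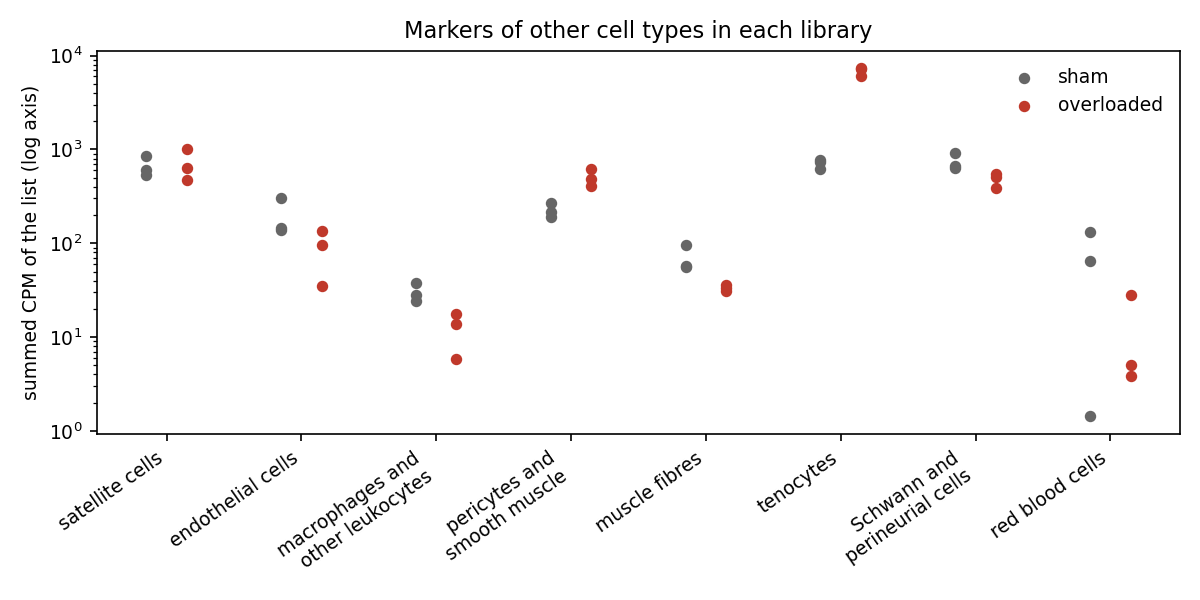
Summed CPM of 8 lists of marker genes of other cell types in each library on a log axis, with grey points for the 3 sham and red points for the 3 overloaded libraries. Tenocyte markers sum to a mean of 710 CPM in sham and 6904 CPM in overloaded libraries, and the other lists to means under 1000 CPM in both groups.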

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

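The covariate for background reads was chosen after the result was seen, as were 10 of the 21 settings for single named genes; the other alternatives were chosen before. In none of the alternatives was a gene called in the direction opposite to its main call. The count of higher and lower genes moved by over 1.5 times with a stricter adjusted p of 0.01 (703 and 618), with a test against a fold of 1.5 (488 and 470), where the stricter criterion itself is the cause, and with the background covariate (488 and 381), which keeps 39.7% of the calls. All other settings, which changed the scaling, the filter, the test, the depth or the genes used, stayed within 1.5 times of 1084 and 1027. Leaving out each replicate in turn gave 853 to 1073 higher and 742 to 960 lower genes. Scaling by library size only gave 971 and 1157, and shifted the median log2 fold change of all genes by -0.07. Correlations of the deviations of libraries with the same number were 0.008, 0.014 and 0.015. Other pairs of a sham and an overloaded library had -0.025 to 0.011. This shows no pairing by number but cannot exclude it, as counting noise also brings such correlations near 0. With the replicate number as a block there were 1043 higher and 993 lower genes and 93.8% of the calls were shared. The 18 list calls by camera fell to 0 with the estimated correlation and stayed at 18 with the block, with library size only and in each fit without 1 library. Fry, which does not set a list against the other genes, gave 22. The list with more lower than higher genes changed side for YAP and TAZ targets without the count filter (3 higher, 2 lower), and for matrix proteases (5 and 4) and TGF-beta and BMP signalling (6 and 4) with the covariate. In the 11 settings planned for named genes, 1229 of 1236 combinations of a gene and a setting kept the direction and the side of the threshold, and the other 7 concern Pdgfra, Yap1 and mt-Atp6. In the 10 settings added, 1076 of 1098 kept their side of the threshold; 17 lost a call, of which 8 with the background covariate, 7 at a fold of 1.5, 1 at an adjusted p of 0.01 and 1 with thinning and block, and 5 gained one. Among the named genes, no called one reversed. Ccn1, called in no setting, went from a log2 fold change of 0.31 to -0.34 with the background covariate. The genes that lost a call were Ccdc80, F3, Lama2, Tcf7l2, Wnt5a, Csf1, B2m, Apoe, Atp5b, mt-Nd1, mt-Atp6 and Ltv1. With a minimum count of 30, 18 named genes were not tested. In the simulation 2 of 200 genes changed by a fold of 1.5 were recovered, so small changes could be missed. The simulation changed 200 of 7207 genes, while 29.3% of the genes tested here were called, and it did not vary depth. Its recovery shares therefore need not hold for this comparison.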

Other observations

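The tests on tenocytes, on immediate early genes and on other splits of the libraries were chosen only after the result was seen, and the gene lists for amino acid, polyamine, retinoid and glucocorticoid genes were prompted by genes seen to change, with the prompting genes left out of each test. Fisher's exact test treats the genes of a list as independent, and genes that move together can make its p too small. These lists were not tested with camera, so their p-values cannot be set beside those of the 25 lists. Psat1, an enzyme of serine synthesis, rose from 44.5 ± 15.1 to 252 ± 15.4 CPM (SD, n = 3; log2 fold change 2.53, SE 0.26, edgeR adjusted p = 8.95e-09), Mthfd2, of mitochondrial one-carbon metabolism, by a log2 fold change of 2.83 (SE 0.34) and the branched-chain aminotransferase gene Bcat1 by 2.94 (SE 0.36). Of 8 further serine, one-carbon and proline genes tested, 6 rose and 0 fell, an odds ratio of 17.1 (Fisher's exact test, adjusted p = 0.000601 over 5 lists), among them Shmt2 (log2 fold change 1.89) and the amino acid transporter gene Slc7a5 (1.81). Of 20 genes for cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 13 rose and 0 fell, an odds ratio of 10.6 (Fisher's exact test, adjusted p = 2.6e-06), with Vars at a log2 fold change of 1.74 and Gars at 1.69.

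Some genes that glucocorticoids are known to induce fell and others did not pass the test. Tsc22d3, encoding the glucocorticoid-induced leucine zipper, fell from 276 ± 60.7 to 31.5 ± 8.84 CPM, and Cdkn1c, a cell cycle inhibitor, from 257 ± 26.0 to 36.0 ± 16.8 CPM. Of 12 other such genes tested, 5 fell, among them Klf9 (log2 fold change -1.04) and Txnip (-1.52), 1, Ddit4, rose and 6 were not called, an odds ratio of 4.33 (Fisher's exact test, adjusted p = 0.0319). Fkbp5, a widely used readout of the receptor, was at 52.9 ± 4.60 and 31.4 ± 1.18 CPM and did not pass the test (edgeR adjusted p = 0.0619), and Per1 was at 26.9 ± 7.0 and 23.8 ± 16.9 CPM. Sgk1, Mt2, Errfi1 and Nfkbia were the others not called. Srm, a polyamine synthesis enzyme, rose by a log2 fold change of 2.28 (SE 0.25), but of 7 other polyamine genes 1 rose and 2 fell, an odds ratio of 0.942 (Fisher's exact test, adjusted p = 1). Rdh10, Aldh1a2 and Aldh1a3, which make retinal and retinoic acid, rose by log2 fold changes of 2.72, 1.79 and 2.67. Of 10 other retinoid genes 2 rose and 4 fell, an odds ratio of 1.42 (Fisher's exact test, adjusted p = 0.816). Those that fell included Aldh1a1, at a log2 fold change of -1.57, and Cyp26b1, which degrades retinoic acid, at -2.24.

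Reads of receptor genes silent in FAPs, and of lincRNA genes, were more frequent in sham libraries, so genes called lower may reflect a higher background there. Scaled to each gene's exon length, this background accounted for a median of 0.0186 of the drop in CPM of the 1027 lower genes (90th percentile 0.0656), and for 0.5 or more in 2 genes. The estimate takes background as even along exons and as high at other genes as at receptor genes. Libraries tagged near the 3' end of transcripts need not follow this, so the estimate does not decide whether background caused the falls. With the background share as a covariate, 488 higher and 381 lower genes passed. The median log2 fold change of the 1027 lower genes was -1.22 without and -1.16 with the covariate and all 1027 kept their direction, while the median SE went from 0.30 to 0.43, so calls ended mainly because the error grew. The covariate differs between the groups and also takes up a residual degree of freedom out of 4, and these effects on the error were not separated. An effect of load on these genes stays open as a hypothesis, untested apart from the comparison itself.

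Tenocytes let through by the Pdgfra gate could raise Thbs4 and Cilp. They would bring their other transcripts too, but the 8 remaining markers of the list changed by -0.66 on the log2 scale (pooled SD 0.45), against 3.28 for the whole list, and the tendon genes Tnmd and Scx had 4 to 7 and 0 to 12 counts in the overloaded libraries, against 0 to 4 and 1 to 2 in sham. The fall of that sum rests largely on Angptl7, with 101, 66 and 122 counts in sham and 46, 27 and 59 in overloaded libraries. Comp had 1, 4 and 6 counts in sham and 20, 4 and 12 in overloaded libraries. As a sum the 8 markers did not rise with Thbs4 and Cilp, which argues against tenocytes as the main cause. The argument is weak, as several of the 8 had few counts. A rise of Thbs4 and Cilp within FAPs stays open as a hypothesis.

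The fall of Fos, Fosb and Egr1 could reflect less stress during dissociation of overloaded muscle, since these genes respond to handling. The 5 heat shock genes of the same list, which handling also induces, had a median log2 fold change of -0.59 and 3 of them fell, which goes with that explanation for the members that fell. It leaves out the 6 members that rose, such as Ier3 (log2 fold change 1.76) and Nr4a2 (1.77), which less handling would not raise. How each library was dissociated is not given in the sources used here, so less handling and the load itself both stay open for the members that fell.

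Among the 10 ways to split the 6 libraries into groups of 3, only the real one gave as many genes in either direction, 1 of 10, with 1084 higher and 1027 lower genes against 0 in every other split by edgeR, where 60 to 205 genes had an unadjusted p under 0.05. Every other split mixes sham and overloaded libraries, so the difference between them adds to the spread within each group and few calls can arise. The contrast with 0 therefore says little, and with 10 splits the share cannot go under 0.05. The ratio of mt-Nd6 to mt-Nd5 counts, from overlapping genes on opposite strands of the mitochondrial genome, was 1.04, 1.05 and 0.970 in sham and 1.51, 1.67 and 1.6 in overloaded libraries.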
